A study of Homo sapiens with 9 samples.

How the data were processed

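The deposited table held 19389 genes by 9 libraries. The libraries were mRNA libraries made with an MGIEasy directional kit. The authors named Trim Galore for trimming, STAR for alignment to hg38 and HTSeq for counting, with no versions. The signal values were deposited after the authors had normalized them for transcript length and depth, but whether as FPKM or TPM is not stated. They are not counts, so the planned count-based alternatives were not run, and how multi-mapped reads were handled is not known.

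The groups, comparisons, gene lists, threshold, naming rule and the alternatives called planned were chosen before the data were examined. A gene was tested when its value was at least 1 in at least 3 libraries, which left 11924. A pseudocount of 1 was added before taking log2. limma 3.58.1 in R 4.3.3 was fitted with a trend of variance on mean to all 9 libraries in 1 model with a mean per group and 6 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in each of 3 comparisons, 2-sided. No replicate block was used because the labels do not pair the libraries. An exact permutation of 3 against 3 libraries cannot give a p under 0.1, so single genes were tested only in the shared model.

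The 35 gene lists held 572 entries, of which 550 matched a symbol in the table, directly or through an older symbol, and 33 lists had tested members. The mitochondrially encoded and endothelial lists had none. The lists covered NF-κB signalling and feedback, cytokines, chemokines, interferon response, antigen presentation, matrix proteases and their inhibitors, fibrillar and pericellular matrix, collagen processing, cartilage matrix and chondrocyte identity, and prostaglandin and nitric oxide. They also covered TGF-β and BMP response, G1/S, G2/M, replication histones, p53 targets, apoptosis regulators, ATF4 and unfolded protein response, heat shock, NRF2 targets, AHR targets, metallothioneins and zinc, glycolysis and hypoxia, oxidative phosphorylation, sterol synthesis, fatty acid synthesis, glucocorticoid response, immediate early genes, ribosomal proteins and markers of other cell types. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. Members were also adjusted over the list alone.

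Genes were named by rule. In each comparison these were the 6 largest called changes in each direction with a mean of at least 5 in the higher group and no overlap between the groups. Added to them were up to 4 members with the smallest p of each called list and of the lists for cytokines, chemokines, NF-κB, matrix proteases, cartilage and prostaglandin. MMP1, MMP3, MMP13, IL6, CXCL8, PTGS2, ADAMTS4, ADAMTS5, COL2A1, ACAN and SOX9 were always included, as were the 6 genes with the largest opposed changes. Positions come from GENCODE 29.

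Overlaps of calls were set beside 100 simulated sets in which no gene changed and the IL-1β libraries were shared. The table had 27 symbols turned into dates, of which 20 passed the filter and were tested without a name, and 14 repeated symbols that were kept as separate entries. In a self-test, 200 of 11924 genes were changed in each of 20 simulated sets. At a log2 change of 0.5, between 91.5% and 92.5% were called, and at 1 between 99.6% and 100%. Unchanged genes made up 5.53%, 4.82% and 5.18% of the called genes on average in the 3 comparisons, and up to 10.3% in a single set. The simulated genes were independent, with the same SD in every group, as the model assumes. These percentages thus check the procedure and do not give its error in the real data. There, genes were correlated and the residual SD of a library ran from 0.0759 to 0.131. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.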

Results

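RNA was measured in SW1353 cells, a human chondrosarcoma line often used as a stand-in for chondrocytes, in 3 groups of 3 libraries. The first group was untreated. The second received interleukin-1β (IL-1β), an inflammatory cytokine, at 20 ng/mL for 20 h. The third received PBSL, a preparation of larvae of the beetle Protaetia brevitarsis seulensis, for 2 h before the same IL-1β exposure. No group received PBSL alone. The PBSL concentration used for the sequenced libraries is not stated. Whether the replicates of a group came from separate cultures is not stated either, so every p-value measures only the spread between these libraries.

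The deposited values were normalized for transcript length and depth, and they summed to between 523758 and 553196 per library. Between 15748 and 16137 genes had a value above 0 in a library, and between 11562 and 11727 reached 1. The 10 most abundant genes held 9.54% to 10.8% of the summed values. The values are not counts, so the number of reads behind each one is unknown. Of 19389 rows, 11924 had a value of at least 1 in at least 3 libraries and were tested. Expression values are given below as means ± SD over the 3 libraries of a group, and log2 fold changes were fitted after adding 1 to each value.

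The first principal component, with 68.7% of the variance, set the untreated libraries (-32.2 to -30) apart from both IL-1β groups (15.1 to 16). The second, with 16.6%, set IL-1β alone (11.5 to 12.4) apart from PBSL 2 (-18.2) and PBSL 3 (-16.8). PBSL 1 lay between these at -0.578.

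**Figure D1:**
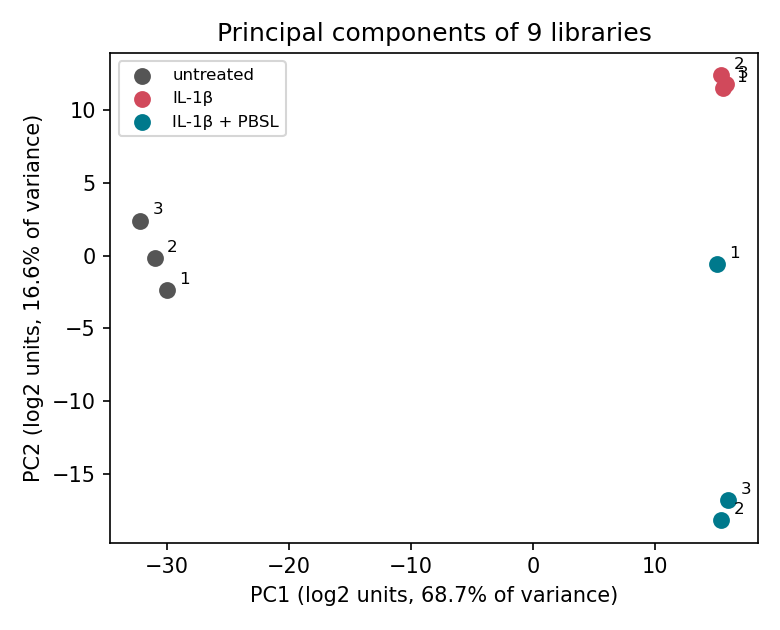
Positions of the 9 libraries on the first 2 principal components of the log2 values of the tested genes, in log2 units, with each point 1 library labelled by its replicate number. On the second component PBSL 1, at -0.578, lies between the IL-1β libraries, at 11.5 to 12.4, and the other PBSL libraries, at -18.2 and -16.8.

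The first comparison asked what IL-1β alone changed in the cells. Chemokines, cytokines and 15 of 19 matrix-degrading proteases were higher after 20 h of IL-1β. CXCL8, a neutrophil-attracting chemokine on chromosome 4 (hg38, 73740506 to 73743716), rose from 2.30 ± 0.403 to 1021 ± 25.3, a log2 fold change of 8.28 (SE 0.0734, adjusted p = 6.07e-15). IL1B, which encodes the cytokine itself, rose from 0.921 ± 0.307 to 111 ± 3.25. The largest falls were in LGR5, a Wnt-pathway receptor, with a log2 fold change of -2.54, and in BMP4, a bone morphogenetic protein, with -2.08. CTGF, a matrix protein gene now named CCN2, fell from 58.9 ± 3.52 to 16.3 ± 0.579. In all, 1928 genes were higher and 1903 lower, which is 32.1% of the genes tested, and 266 of the higher and 65 of the lower genes had a fitted change of at least 2-fold. The 3 libraries of one group lay wholly above those of the other for 52.8% of all tested genes, called or not, where chance gives 10%. With a trend on transcript length and GC content removed, a check added after the values were seen, 1946 genes were higher and 2859 lower.

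Every tested member rose in the NF-κB signalling and feedback list, 23 of 23, with a mean log2 fold change of 2.07 (adjusted p = 1.17e-27). Among them SOD2, a mitochondrial superoxide dismutase, rose from 35.7 ± 1.11 to 1325 ± 15.8, and ZC3H12A, an RNase that degrades cytokine transcripts, from 4.08 ± 0.502 to 59.2 ± 2.6. All 13 tested cytokines rose by a mean of 2.98 (adjusted p = 6.75e-19), with IL6 going from 0.16 ± 0.171 to 44.6 ± 1.81 and LIF from 1.75 ± 0.168 to 22.7 ± 0.474. All 14 tested chemokines rose by a mean of 3.45 (adjusted p = 1.14e-19), including CXCL5, which went from 0.145 ± 0.0189 to 52.0 ± 0.0733, and CCL2, a monocyte attractant, from 3.33 ± 0.285 to 125 ± 2.62. The counts of these 3 lists were the same when adjusted over the list alone. The cytokine and chemokine lists each had 18 genes in the table, and the untested ones were below the filter. A gene near 0 in untreated cells passed it only by reaching 1 in libraries given IL-1β. Members that stayed near 0 thus could not count against these shares, which holds for every list and also for PBSL against untreated cells. With an estimated correlation between genes the 3 lists stayed called, at adjusted p = 0.00285 for the NF-κB list, 0.00285 for cytokines and 0.0191 for chemokines. How reads shared between similar genes, such as CXCL1, CXCL2 and CXCL3, were counted is not stated.

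All tested interferon-response and antigen-presentation genes were also higher, but the calls of both lists were lost with an estimated correlation. All 27 tested interferon-response genes rose, by a mean of 2 (adjusted p = 4.11e-23 with the preset correlation, adjusted p = 0.142 with an estimated correlation). OAS3, an antiviral enzyme, rose from 7.09 ± 0.176 to 43.2 ± 1.53, and IRF1, a transcription factor, from 9.41 ± 0.428 to 23.3 ± 0.833. All 15 antigen-presentation genes rose, by a mean of 0.951 (adjusted p = 8.84e-14, and adjusted p = 0.117 with an estimated correlation). TAPBP, which helps load peptides onto class I molecules, had a log2 fold change of 1.21. Both counts were the same when adjusted over the list alone. The estimated correlation, 0.779 for the interferon list, came from residuals of all 9 libraries, the PBSL libraries included. Mean log2 values of the interferon list were 2.25 to 2.32 in untreated libraries and 4.23 to 4.35 with IL-1β. By limma's fry, which does not compare a list with other genes, the adjusted p was 8.91e-05 for interferon response and 5.31e-05 for antigen presentation.

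Of 19 matrix proteases tested, 15 rose and none fell, and the count was the same adjusted over the list alone (adjusted p = 2.51e-11, and adjusted p = 0.0112 with an estimated correlation). MMP3, or stromelysin 1, rose from 127 ± 5.64 to 1195 ± 21.7. The collagenases MMP1 and MMP13 rose from 10.9 ± 0.296 to 131 ± 4.82 and from 2.14 ± 0.364 to 76.2 ± 9.26. MMP1, MMP3 and MMP13 lie within 102789920 to 102955734 on chromosome 11. The aggrecanase genes ADAMTS4 and ADAMTS5 were below the filter, with highest library values of 0.024 and 0.344. Of 8 protease inhibitors, 5 rose and 1 fell (adjusted p = 0.000249, and adjusted p = 0.0361 with an estimated correlation), and 6 rose and 1 fell adjusted over the list alone. The gene that fell, TIMP2, was named after its values were seen, and its call was lost without IL-1β 1 (adjusted p = 0.0582), without IL-1β 3 (adjusted p = 0.054) and without untreated 3 (adjusted p = 0.0686), in a range of 0.00488 to 0.0686. SERPINB2, a plasminogen activator inhibitor, rose from 3.38 ± 0.518 to 240 ± 8.85.

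The few tested cartilage genes did not move as a group. Only 6 of the 22 list genes in the table passed the filter. Of these 6, 3 rose and 3 fell, also when adjusted over the list alone. The list was not called (adjusted p = 0.915, mean 0.151, median -0.0127). ACAN, COL10A1 and RUNX2 rose, and SOX9, COL11A1 and HAPLN1 fell. ACAN, which encodes the proteoglycan aggrecan, rose from 0.501 ± 0.0503 to 1.43 ± 0.201, while SOX9, a chondrocyte transcription factor, fell from 12.02 ± 0.68 to 8.80 ± 0.371. COL2A1, the type II collagen gene, was below the filter, with a highest library value of 0.027. Of 8 prostaglandin and nitric oxide genes, 4 rose and 1 fell, also when adjusted over the list alone, and the list was not called (adjusted p = 0.12). PTGS2, which encodes cyclooxygenase 2, rose from 0.836 ± 0.206 to 7.76 ± 0.294.

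In the fibrillar and pericellular matrix list, 9 of 20 genes rose and 3 fell, also when adjusted over the list alone, among them the proteoglycan DCN, which rose from 11.8 ± 1.27 to 128 ± 2.6, and FN1, or fibronectin, from 763 ± 38.8 to 1337 ± 13.1. Its call (adjusted p = 0.0407) was lost with an estimated correlation (adjusted p = 0.726), without untreated 1 (adjusted p = 0.0765), without IL-1β 2 (adjusted p = 0.0586) and with a replicate block (adjusted p = 0.0511). Over the alternatives at the preset correlation, these included, the adjusted p of this list ran from 0.0162 to 0.0765; every range given for a list covers these alternatives, without the estimated correlation and fry. Of 12 collagen-processing genes, 8 rose and 1, PCOLCE, fell, also when adjusted over the list alone (adjusted p = 0.000716, and adjusted p = 0.398 with an estimated correlation). PLOD2, a collagen lysyl hydroxylase, rose from 83.2 ± 2.95 to 286 ± 5.86.

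All 6 metallothionein and zinc genes rose, also when adjusted over the list alone (adjusted p = 6.34e-08, and adjusted p = 0.0276 with an estimated correlation), with MT2A, a metal-binding protein, going from 930 ± 41.5 to 4087 ± 106. Of 23 ATF4 and unfolded protein response genes, 21 rose, and 22 adjusted over the list alone (adjusted p = 9.81e-10, and adjusted p = 0.174 with an estimated correlation). HSPA5, the endoplasmic reticulum chaperone BiP, rose from 236 ± 3.18 to 358 ± 3.6. Of 20 glycolysis and hypoxia genes, 13 rose, also when adjusted over the list alone (adjusted p = 3.06e-09, and adjusted p = 0.0627 with an estimated correlation). Of 12 apoptosis regulators, 8 rose and BCL2L1, named after its values were seen, fell, and 9 rose and 2 fell adjusted over the list alone (adjusted p = 0.000875, and adjusted p = 0.0447 with an estimated correlation). BCL2A1, which blocks apoptosis, rose from 0.205 ± 0.156 to 4.75 ± 0.256, and BID, which promotes it, from 9.56 ± 0.556 to 21.2 ± 0.519.

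Of 18 genes of G1/S phase and replication, 11 fell, and 13 adjusted over the list alone (adjusted p = 0.000191, and adjusted p = 0.528 with an estimated correlation). MCM6, a subunit of the replicative helicase, fell from 22.5 ± 2.3 to 15.1 ± 0.526. Of 20 oxidative phosphorylation genes, 12 fell, also when adjusted over the list alone (adjusted p = 3e-04, and adjusted p = 0.236 with an estimated correlation). Of 22 ribosomal protein genes, 5 fell, and 3 adjusted over the list alone (adjusted p = 0.00724, and adjusted p = 0.528 with an estimated correlation). The ribosomal call was lost without untreated 3 (adjusted p = 0.053), and over the alternatives at the preset correlation it ran from 0.00014 to 0.053.

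Of 5 replication histone genes that are seen in poly(A) libraries, 4 rose, also when adjusted over the list alone (adjusted p = 0.0183). This call was lost with an estimated correlation (adjusted p = 0.371) and with the length and GC trend removed (adjusted p = 0.0715, in a range of 0.00701 to 0.0715). Among lists of other cell types, the 3 tested macrophage markers CD68, CSF1R and FCER1G rose, also when adjusted over the list alone (adjusted p = 0.0169, and adjusted p = 0.122 with an estimated correlation). CD68, which is expressed in many cell types, went from 71.6 ± 3.67 to 95.7 ± 1.75. Named after their values were seen, CLDN4 rose and KRT8 and KRT18 fell among 3 epithelial markers, CD3E fell of 2 lymphocyte markers, and DES fell as the 1 adipocyte and muscle marker tested. The call of CD3E was lost without IL-1β 3 (adjusted p = 0.0659) and without untreated 1 (adjusted p = 0.0569), in a range of 0.00351 to 0.0659. No endothelial marker passed the filter, and mitochondrially encoded genes were not analysed here.

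The remaining lists were not called, with adjusted p from 0.0973 to 0.943 across all uncalled lists. Of 18 genes of G2/M phase and mitosis, 2 rose, with a call only without untreated 1 (adjusted p = 0.0239) and with no filter on the genes outside the list (adjusted p = 0.0478) in a range of 0.0239 to 0.412. Of 22 NRF2 targets 7 rose and 8 fell, with a mean of 0.0179 and a median of -0.0217, of 20 sterol synthesis genes 2 rose and 5 fell, and of 18 immediate early genes 5 rose and 7 fell. Of 14 p53 targets 5 rose and 2 fell, of 12 TGF-β and BMP genes 4 rose and 3 fell, and of 11 heat shock genes 1 rose and 4 fell. Of 9 fatty acid synthesis genes 3 rose and 3 fell, of 7 glucocorticoid-responsive genes 3 rose and 2 fell, and of 4 AHR targets 1 rose and 1 fell. Adjusted over the list alone, 3 rose and 6 fell for sterol synthesis, 7 and 8 for immediate early genes, 6 and 4 for TGF-β and BMP, 1 and 5 for heat shock, and 1 and 1 for lymphocyte markers; the others were the same.

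Genes were tested with limma over all 9 libraries and lists with limma's camera at a preset correlation of 0.01. Of the 87 genes that the naming rule picked in this comparison, all were called, and the libraries of the groups did not overlap for 86, which the rule required of some. The exception was HIST1H2BD, whose call was lost without IL-1β 1, IL-1β 3, untreated 1 or untreated 2 (adjusted p = 0.0865, 0.0602, 0.0772 and 0.0592 in this order), in a range of 0.00238 to 0.0865. The HIST1H2BD call was also lost with no filter (adjusted p = 0.0529) and with the length and GC trend removed (adjusted p = 0.0832). All 18 called lists had library means that did not overlap between the groups.

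The second comparison asked what PBSL changed in cells given IL-1β. Interferon-response genes and matrix genes were lower and cell-cycle genes higher with PBSL, while the NF-κB list was not called. These list calls rest on the preset correlation: with an estimated correlation the adjusted p was 0.229 for the interferon list and 0.183 for the fibrillar matrix, G1/S and G2/M lists, and the interferon to NF-κB difference had p = 0.0941. IFI27, an interferon-induced gene on chromosome 14 (94104836 to 94116698), fell from 147 ± 3.7 to 37.1 ± 26.2, a log2 fold change of -2.18 (SE 0.34, adjusted p = 0.00337). ISG15, a ubiquitin-like modifier on chromosome 1 (1001138 to 1014540), fell from 201 ± 9.31 to 74.7 ± 36.3 (log2 fold change -1.52, SE 0.231, adjusted p = 0.00315). CNN1, which encodes the actin-binding protein calponin 1, fell by 1.31 on the log2 scale. Among the largest increases was IL1RN, the interleukin-1 receptor antagonist, from 7.78 ± 1.05 to 14.8 ± 3.86 (log2 fold change 0.82).

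In all, 1370 genes were higher and 1314 lower with PBSL, which is 22.5% of the genes tested, with a median absolute log2 fold change of 0.324 among them. By limma, none of the higher genes and 18 of the lower ones had a fitted change of at least 2-fold with 1 added to each value, and 4360 genes had an unadjusted p under 0.05. The 0 depends on the pseudocount and on PBSL 1. ESM1, a secreted proteoglycan, went from 2.843 ± 0.252 to 6.812 ± 2.94, with a log2 fold change of 0.952 as fitted, 1.14 with a pseudocount of 0.1 and 1.26 without PBSL 1. SLCO4A1, an organic anion transporter, went from 3.585 ± 0.358 to 7.544 ± 2.28, with 0.867, 1.01 and 1.05 in the same order. The libraries did not overlap for 41.8% of all tested genes, where chance gives 10%. The split between higher and lower depended on scaling. As deposited, 51% of the called genes were higher, and after median-ratio rescaling, added after the values were seen, 1035 were higher and 1704 lower, or 37.8% higher. The counts also moved with single libraries. Higher and lower genes numbered 718 and 730 without IL-1β 1, 650 and 664 without IL-1β 2, 682 and 678 without IL-1β 3, and 713 and 723 without PBSL 2. Without PBSL 1, which lay between the groups, 3904 genes were called, and 2627 of these were among the 2684 and had the same direction.

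**Figure D2:**
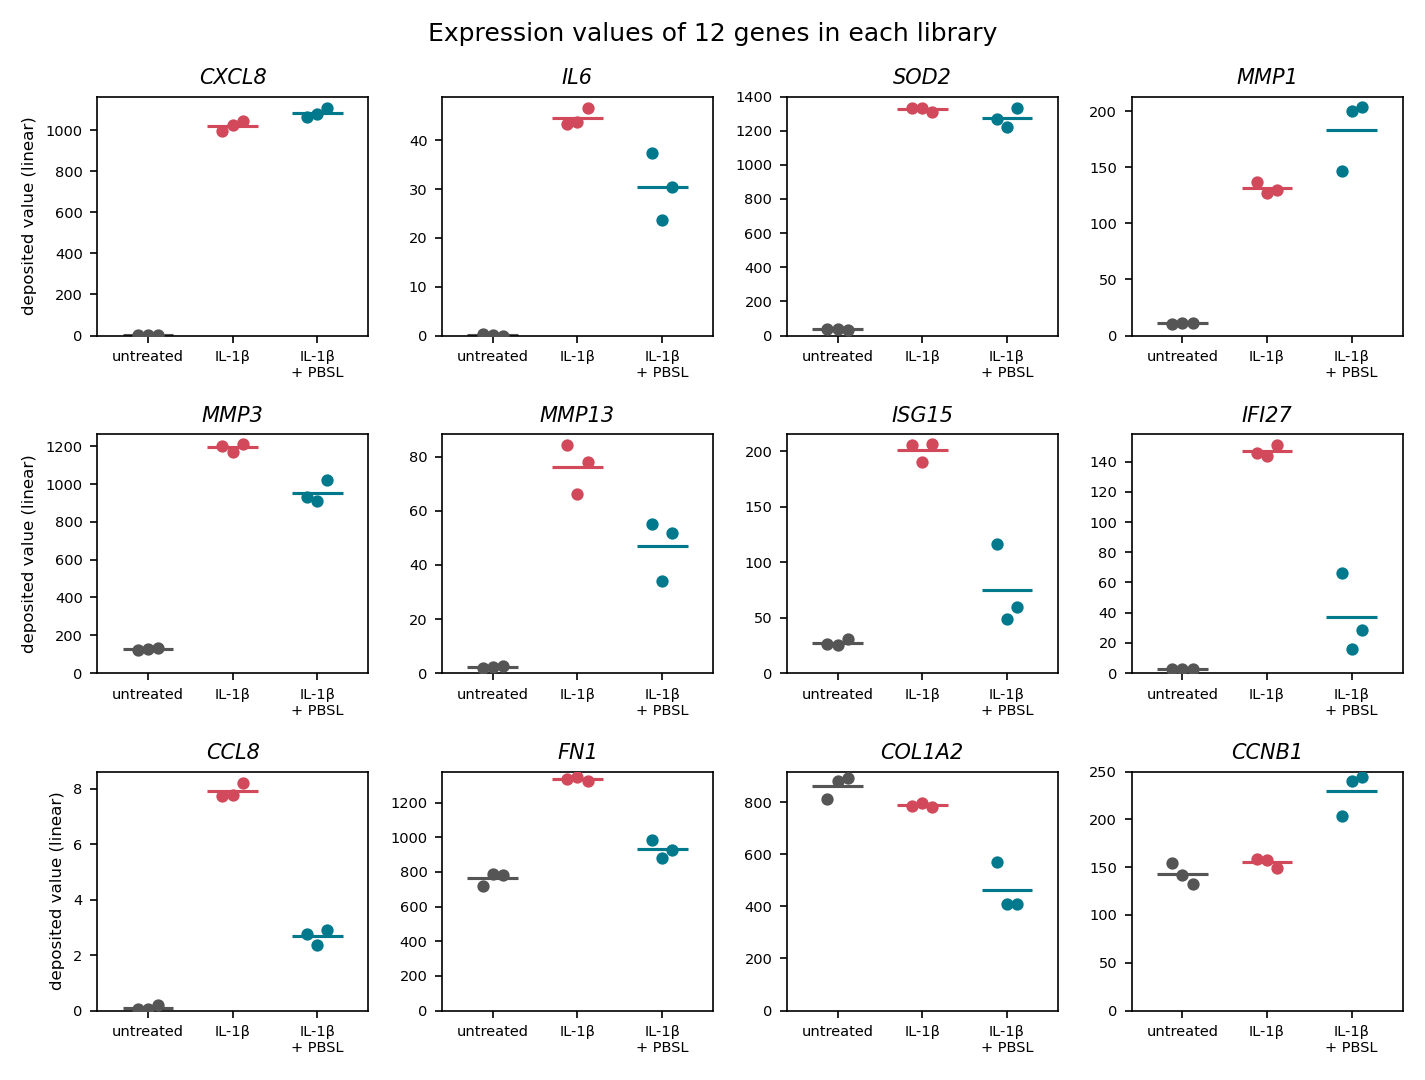
Expression values of 12 genes in each of the 9 libraries on linear axes, as deposited, with a point per library and a line at the mean of each group of 3. IFI27 and ISG15 were lower with PBSL in all 3 libraries than with IL-1β alone, and CXCL8 was at 1021 ± 25.3 with IL-1β and 1083 ± 22.7 with PBSL.

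Of 27 interferon-response genes, 22 fell and none rose, and 24 fell adjusted over the list alone, with a mean log2 fold change of -0.76 (adjusted p = 5.96e-13, and adjusted p = 0.229 with an estimated correlation). BST2, or tetherin, which holds budding viruses at the cell surface, fell from 31.9 ± 4.82 to 10.3 ± 5.66, and XAF1, an interferon-induced apoptosis factor, from 1.48 ± 0.137 to 0.474 ± 0.28. Relative to the mean of the IL-1β libraries, the list stood at -0.357 in PBSL 1, -1.15 in PBSL 2 and -0.756 in PBSL 3. Of 15 antigen-presentation genes, 12 fell, and 14 adjusted over the list alone (adjusted p = 3.32e-09, and adjusted p = 0.183 with an estimated correlation), with -0.214 in PBSL 1, -0.467 in PBSL 2 and -0.52 in PBSL 3. B2M, the light chain of class I molecules, fell from 1471 ± 63.2 to 1104 ± 110, and HLA-B from 322 ± 7.27 to 203 ± 43. The HLA genes resemble each other, and how reads shared between them were counted is not stated.

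The NF-κB list was not called (adjusted p = 0.279). Of its 23 genes 19 were not called, TNFAIP2, ICAM1 and BIRC3 fell and CD83 rose, and the counts were the same adjusted over the list alone. SOD2 stood at 1325 ± 15.8 with IL-1β and 1273 ± 57.8 with PBSL. ICAM1, an adhesion molecule, fell from 14.7 ± 1 to 9.84 ± 1.13. The calls of ICAM1 and BIRC3 were lost with a pseudocount of 0.1 (adjusted p = 0.0869 and 0.057), in ranges of 0.0016 to 0.0869 and 0.00293 to 0.057. That of CD83 was lost without IL-1β 1 (adjusted p = 0.0579) and without IL-1β 2 (adjusted p = 0.055), in a range of 0.00973 to 0.0579. The interferon list changed by -0.703 more than the NF-κB list on the log2 scale (p = 2.25e-07 with the preset correlation, p = 0.0941 with an estimated correlation). It changed by -0.538 more than the cytokine list (p = 0.00223, and p = 0.261 with an estimated correlation) and by -0.27 more than the chemokine list (p = 0.257, and p = 0.684 with an estimated correlation).

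Of 14 chemokines, 8 fell and none rose, and 9 fell adjusted over the list alone (adjusted p = 1.15e-05, and adjusted p = 0.183 with an estimated correlation). CCL8 fell from 7.93 ± 0.256 to 2.69 ± 0.292 and CXCL5 from 52.0 ± 0.0733 to 29.1 ± 2.24. CXCL8 was not called, with a log2 fold change of 0.09 (adjusted p = 0.431). The list stood at -0.351 in PBSL 1, -0.63 in PBSL 2 and -0.473 in PBSL 3. Of 13 cytokines 5 fell, and 6 fell and 1 rose adjusted over the list alone (adjusted p = 0.0175, and adjusted p = 0.183 with an estimated correlation). IL11 fell from 109 ± 3.69 to 69.6 ± 7.14 and IL32 from 163 ± 11.4 to 100.2 ± 23.2. The cytokine list stood at -0.132, -0.226 and -0.294 in PBSL 1, 2 and 3, and its call was lost without PBSL 3 (adjusted p = 0.0624, in a range of 0.00703 to 0.0624). IL6 went from 44.6 ± 1.81 to 30.4 ± 6.9 (log2 fold change -0.56, adjusted p = 0.0175). Its call was lost without IL-1β 2 (adjusted p = 0.0509), without IL-1β 3 (adjusted p = 0.0615), without PBSL 2 (adjusted p = 0.0588), with no filter (adjusted p = 0.0545) and with a pseudocount of 0.1 (adjusted p = 0.313), in a range of 0.00156 to 0.313.

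Of 19 matrix proteases 7 fell and 2, MMP1 and MMP9, rose, and 7 fell and 3 rose adjusted over the list alone (adjusted p = 0.0146, and adjusted p = 0.183 with an estimated correlation). MMP13 fell from 76.2 ± 9.26 to 47.0 ± 11.4 (log2 fold change -0.71, adjusted p = 0.0101), and MMP3 from 1195 ± 21.7 to 955 ± 57.6 (log2 fold change -0.32, adjusted p = 0.00405). MMP7, or matrilysin, fell from 7.04 ± 0.434 to 2.65 ± 0.595. In contrast MMP1 rose from 131 ± 4.82 to 184 ± 31.8 (log2 fold change 0.47, adjusted p = 0.00924). MMP9 was named here after its values were seen, and its call was lost without IL-1β 1, IL-1β 2, IL-1β 3, PBSL 2 or PBSL 3 (adjusted p = 0.11, 0.0649, 0.0714, 0.0819 and 0.0664 in this order), in a range of 0.00192 to 0.11. The MMP9 call was also lost with no filter (adjusted p = 0.0879) and with only the 2 compared groups in the model (adjusted p = 0.0584). The list call was lost without PBSL 1 (adjusted p = 0.0771, in a range of 0.00407 to 0.0771), and the list stood at -0.162, -0.165 and -0.109 in PBSL 1, 2 and 3. Of 8 protease inhibitors 5 fell and SERPINB2 rose, also when adjusted over the list alone (adjusted p = 0.0158, and adjusted p = 0.183 with an estimated correlation), with TIMP3 going from 175 ± 1.61 to 128 ± 16.5. The inhibitors stood at -0.149, -0.181 and -0.176 in PBSL 1, 2 and 3. SERPINB2, named in this comparison after its values were seen, lost its call without IL-1β 1, IL-1β 2, IL-1β 3, PBSL 2 or PBSL 3 (adjusted p = 0.083, 0.108, 0.0628, 0.0916 and 0.103 in this order) and with a replicate block (adjusted p = 0.0582), in a range of 0.00667 to 0.108. The SERPINB2 call was also lost with no filter (adjusted p = 0.0719).

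Of 20 fibrillar and pericellular matrix genes, 16 fell and none rose, and 19 fell adjusted over the list alone, with a mean of -0.47 (adjusted p = 1.8e-13, and adjusted p = 0.183 with an estimated correlation). FN1 fell from 1337 ± 13.1 to 931 ± 51.2, COL1A2, a chain of type I collagen, from 787 ± 8.56 to 462 ± 92.1, and COL5A1 from 183 ± 2.21 to 112 ± 21.7. The list stood at -0.296 in PBSL 1, -0.585 in PBSL 2 and -0.529 in PBSL 3. Of 12 collagen-processing genes 10 fell, also when adjusted over the list alone (adjusted p = 2.58e-07, and adjusted p = 0.183 with an estimated correlation), with -0.17, -0.393 and -0.399 in PBSL 1, 2 and 3. SERPINH1, the collagen chaperone HSP47, fell from 418 ± 12.8 to 302 ± 44.1. Of 12 TGF-β and BMP genes 6 fell, and 8 adjusted over the list alone (adjusted p = 6.45e-05, and adjusted p = 0.183 with an estimated correlation), with -0.196, -0.229 and -0.374 in PBSL 1, 2 and 3. ID3, a transcriptional inhibitor, fell from 235 ± 4.62 to 180 ± 13.9.

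Of 6 tested cartilage genes, COL11A1 fell, also when adjusted over the list alone, and the list was not called (adjusted p = 0.195). SOX9 stood at 8.80 ± 0.371 with IL-1β and 8.92 ± 0.816 with PBSL (adjusted p = 0.914). ACAN went from 1.43 ± 0.201 to 1.80 ± 0.354 (adjusted p = 0.186), and it was called without PBSL 1 (adjusted p = 0.044, in a range of 0.044 to 0.498). PTGS2 was not called, at 7.76 ± 0.294 and 8.62 ± 1.38 (adjusted p = 0.422).

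All 18 genes of G1/S phase and replication rose, also when adjusted over the list alone, by a mean of 0.583 (adjusted p = 1.8e-13, and adjusted p = 0.183 with an estimated correlation). TYMS, or thymidylate synthase, rose from 94.3 ± 1.69 to 150 ± 20.1 and MCM4, a helicase subunit, from 32.5 ± 0.54 to 50.6 ± 7.2. The list stood at 0.345 in PBSL 1, 0.747 in PBSL 2 and 0.657 in PBSL 3. All 18 genes of G2/M phase and mitosis rose, also when adjusted over the list alone, by a mean of 0.47 (adjusted p = 2.21e-13, and adjusted p = 0.183 with an estimated correlation), with 0.312, 0.537 and 0.562 in PBSL 1, 2 and 3. CCNB1, or cyclin B1, rose from 155 ± 4.96 to 230 ± 22.3, and the mitotic kinase PLK1 from 75.7 ± 1.28 to 111 ± 11.2. Of 5 replication histone genes 4 fell, and 5 adjusted over the list alone (adjusted p = 0.000852, and adjusted p = 0.183 with an estimated correlation), with -0.234, -0.512 and -0.479 in PBSL 1, 2 and 3.

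Of 11 heat shock genes 6 rose and HSPB1 fell, and 7 rose and 1 fell adjusted over the list alone (adjusted p = 0.000548, and adjusted p = 0.183 with an estimated correlation). HSPE1, a mitochondrial chaperonin, rose from 220 ± 7.62 to 330 ± 38.5. The list stood at 0.148, 0.301 and 0.273 in PBSL 1, 2 and 3. HSPB1, named after its values were seen, lost its call without IL-1β 1, IL-1β 2, PBSL 2 or PBSL 3 (adjusted p = 0.0551, 0.0632, 0.0705 and 0.0539 in this order), in a range of 6.13e-05 to 0.0705. The HSPB1 call was also lost with no filter (adjusted p = 0.058). Of 20 oxidative phosphorylation genes 6 rose, also when adjusted over the list alone (adjusted p = 0.00849, and adjusted p = 0.304 with an estimated correlation), at 0.0738, 0.15 and 0.124. Of 23 ATF4 and unfolded protein response genes 18 fell, and 19 adjusted over the list alone (adjusted p = 4.94e-10, and adjusted p = 0.183 with an estimated correlation), at -0.177, -0.443 and -0.414. ASNS, or asparagine synthetase, fell from 84.3 ± 2.06 to 52.5 ± 11.3.

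Of 6 metallothionein and zinc genes 5 fell, also when adjusted over the list alone (adjusted p = 0.00115, and adjusted p = 0.183 with an estimated correlation), at -0.359, -0.763 and -0.673 in PBSL 1, 2 and 3. MT1X fell from 1183 ± 33.5 to 844 ± 136, and MT2A stood at 4087 ± 106 and 4036 ± 803. The MT1 genes resemble each other, and the counting of their shared reads is not stated. Of 22 NRF2 targets 9 fell and AKR1C1 rose, and 9 fell and 2 rose adjusted over the list alone (adjusted p = 0.00444, and adjusted p = 0.248 with an estimated correlation), at -0.0705, -0.184 and -0.124. TXNRD1, or thioredoxin reductase 1, fell from 272 ± 2.68 to 227 ± 12.9. AKR1C1, named after its values were seen, lost its call without IL-1β 2, IL-1β 3, PBSL 2, PBSL 3 or untreated 2 (adjusted p = 0.161, 0.0877, 0.118, 0.103 and 0.0546 in this order) and with a replicate block (adjusted p = 0.056), in a range of 0.0131 to 0.161. The AKR1C1 call was also lost with median-ratio rescaling (adjusted p = 0.0721), quantile normalization (0.0567) and the length and GC trend removed (0.054). The same held with no filter (0.0754) and with only the 2 compared groups in the model (0.058).

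The remaining lists were not called, with adjusted p from 0.0702 to 0.968 across all uncalled lists. Of 18 immediate early genes 5 rose and 4 fell, of 20 glycolysis and hypoxia genes 4 fell, of 14 p53 targets 3 fell, and of 12 apoptosis regulators 1 rose and 1 fell. Of 22 ribosomal protein genes 3 rose, of 20 sterol synthesis genes 1 fell, of 9 fatty acid synthesis genes 1 rose and 1 fell, and of 8 prostaglandin and nitric oxide genes 1 rose and 2 fell. Of 7 glucocorticoid-responsive genes 1 rose and 1 fell, and of 4 AHR targets CYP1A1 rose and NQO1 fell. Of other cell types, CD68 fell of 3 macrophage markers, KRT8 of 3 epithelial markers, CD3D of 2 lymphocyte markers, and DES as the 1 adipocyte and muscle marker; these and both AHR targets were named after their values were seen. The AHR list had a mean of 0.0149 and a median of -0.0333. The call of NQO1 was lost without IL-1β 1, 2 or 3 or PBSL 2 (adjusted p = 0.0729, 0.0679, 0.0542 and 0.0542), in a range of 0.00307 to 0.0729, and that of CD68 without IL-1β 1 or 3 (adjusted p = 0.0584 and 0.0556), in a range of 0.00539 to 0.0584. The call of KRT8 was lost without any single library except PBSL 1: adjusted p = 0.0901, 0.14 and 0.112 without IL-1β 1, 2 and 3, 0.153 and 0.141 without PBSL 2 and 3, and 0.0583, 0.0673 and 0.0586 without untreated 1, 2 and 3, in a range of 0.000977 to 0.153. The KRT8 call was also lost with a replicate block (adjusted p = 0.0525), no filter (0.091), a pseudocount of 5 (0.0514) and the length and GC trend removed (0.0593). With only the 2 compared groups in the model it was lost too (0.0828). Adjusted over the list alone, 3 fell for glycolysis, none changed for ribosomal or sterol genes, and 3 fell and 1 rose for glucocorticoid-responsive genes; the others were the same. Lists called without a single library were the glucocorticoid list without IL-1β 2 (adjusted p = 0.0495) and without PBSL 1 (adjusted p = 0.0333), in a range of 0.0333 to 0.111, the sterol list without PBSL 1 (adjusted p = 0.023), in a range of 0.023 to 0.924, and the ribosomal list without PBSL 3 (adjusted p = 0.0126), in a range of 0.0126 to 0.452.

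The preset correlation of 0.01 gave 17 called lists, and an estimated correlation none, while limma's fry, which does not compare a list with other genes, gave an adjusted p of 0.0161 for the interferon list and 0.00534 for the G1/S list. In all 17 called lists and in the 87 of 94 named genes that were called, all 3 PBSL libraries lay on the same side of the 3 IL-1β libraries, which the naming rule required of some genes.

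**Figure D3:**
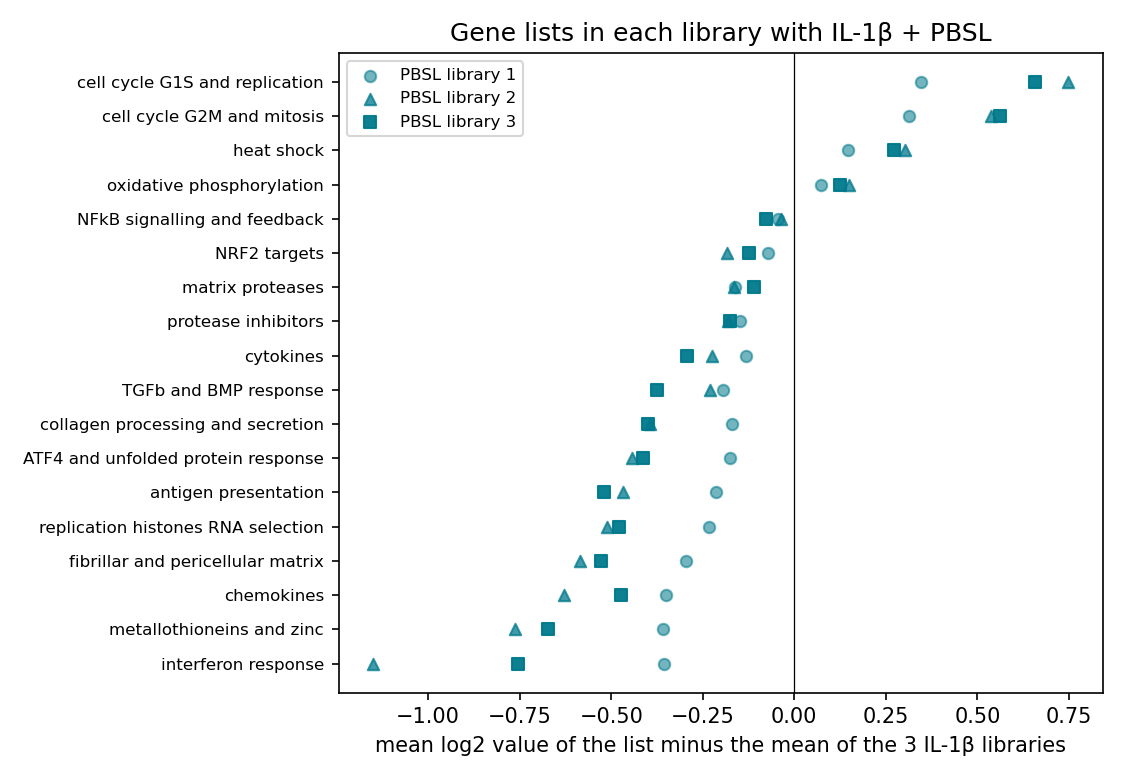
Mean log2 value of each of 18 gene lists in the PBSL libraries minus the mean of the 3 IL-1β libraries, in log2 units, with a symbol per PBSL library. The lists run from G1/S genes, at 0.345, 0.747 and 0.657 in PBSL 1, 2 and 3, to interferon-response genes, at -0.357, -1.15 and -0.756.

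The third question was whether PBSL moved genes back toward their untreated level. Without a group given PBSL alone, opposing IL-1β cannot be told apart from an effect that PBSL has by itself. Of the 1928 genes raised by IL-1β, 513 (26.6%) fell with PBSL and 75 (3.89%) rose further. Of the 1903 lowered by IL-1β, 265 (13.9%) rose with PBSL and 224 (11.8%) fell further. After median-ratio rescaling 216 rose and 292 fell further, so the order of these counts turned. The genes with the largest opposed changes were IFI27, IFITM1, BST2, CXCL5, IFI6 and ISG15. IFITM1, an antiviral membrane protein gene, went from 3.53 ± 1.22 in untreated cells to 68.6 ± 5.06 with IL-1β and 21.8 ± 12.4 with PBSL.

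By list, 22 of 27 interferon-response genes raised by IL-1β fell with PBSL, as did 12 of 15 antigen-presentation genes, 17 of 21 ATF4 and unfolded protein response genes and 8 of 8 collagen-processing genes. Of the 23 NF-κB genes raised by IL-1β 3 fell, of 14 chemokines 8, of 13 cytokines 5 and of 15 matrix proteases 6. Unrelated calls would give 212.5 genes raised and then lowered, 218.6 lowered and then raised, 221.5 raised further and 209.7 lowered further. Both comparisons share the 3 IL-1β libraries, which alone gives opposed changes. Across genes, which are not independent replicates, the covariance of the fold changes was -0.025, and 100 simulated sets with no true change gave -0.00477 to -0.00368. The observed covariance thus lay beyond what sharing the libraries gave in these sets. The correlation was -0.256, against -0.545 to -0.448 in the simulated sets with no true change, and nothing was read from it. Genes raised and then lowered numbered 290 without IL-1β 1, 274 without IL-1β 2, 269 without IL-1β 3 and 329 without PBSL 2. Those lowered and then raised numbered 117, 95, 111 and 178 without the same libraries, 480 without PBSL 1 and 151 without untreated 1. Genes raised further numbered 30, 35, 31 and 43 without IL-1β 1, 2 and 3 and PBSL 2, and 158 without PBSL 1. Genes lowered further numbered 97, 94, 98 and 129, and 381 without PBSL 1.

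**Figure D4:**
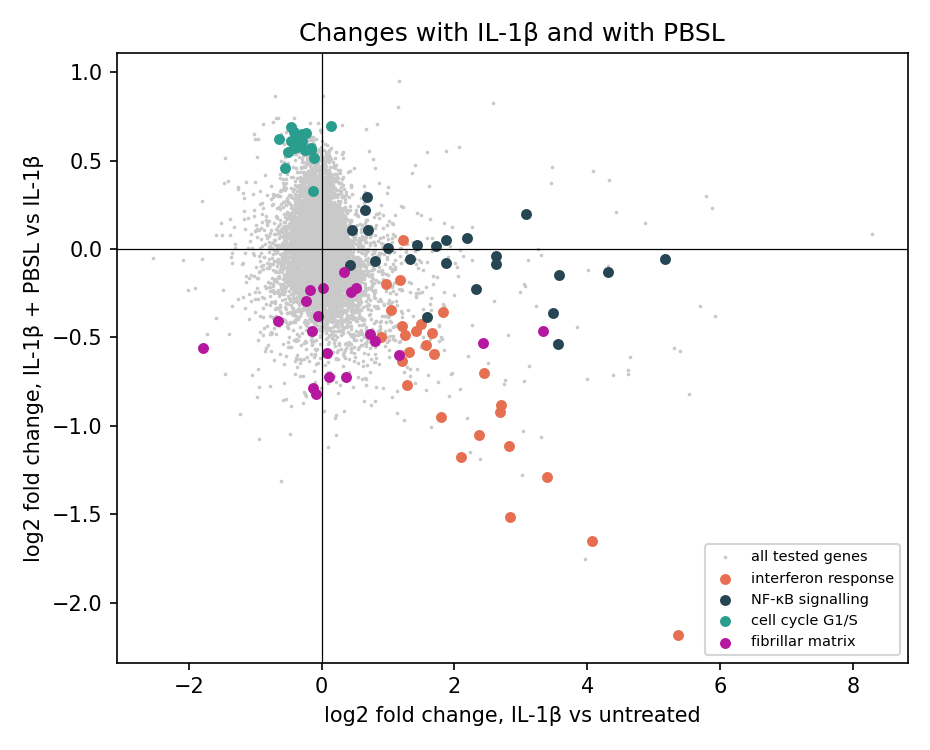
Log2 fold change with PBSL relative to IL-1β alone against log2 fold change with IL-1β relative to untreated cells, with a point per tested gene and 4 gene lists in colour. Interferon-response genes spread downward with a mean of -0.76 on the vertical axis, NF-κB genes stay near 0 with a mean of -0.05, and the 18 G1/S genes lie above 0.

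The fourth comparison asked what differed from untreated cells when both PBSL and IL-1β were present. All 23 NF-κB genes and 12 of 13 cytokines were above the untreated level, and of the 12 called lists these 2 stayed called with an estimated correlation. The chemokine call (adjusted p = 0.0549) and the interferon, antigen-presentation and G2/M calls (adjusted p = 0.278 each) were among those lost with it. CXCL8 was at 1083 ± 22.7 against 2.30 ± 0.403 in untreated cells (log2 fold change 8.37, SE 0.0734, adjusted p = 5.39e-15). ACTA2, or smooth muscle actin, was at 31.1 ± 6.61 against 141 ± 3.46, and FHL1, a LIM-domain protein gene, at 146 ± 30.4 against 647 ± 26.9. In all, 2658 genes were higher and 2307 lower, which is 41.6% of those tested, with a fitted change of at least 2-fold in 202 and 135. The libraries did not overlap for 48.2% of all tested genes, where chance gives 10%. The majority turned with scaling: 2214 genes were higher and 2653 lower after median-ratio rescaling, 2193 and 2618 after quantile normalization, and 2597 and 2928 with the length and GC trend removed, all 3 added after the values were seen.

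All 23 NF-κB genes were higher than in untreated cells (adjusted p = 4.85e-23, and adjusted p = 0.00617 with an estimated correlation), as were 12 of 13 cytokines (adjusted p = 3.75e-14, and adjusted p = 0.00617 with an estimated correlation) and 13 of 14 chemokines (adjusted p = 6.34e-13, and adjusted p = 0.0549 with an estimated correlation). All 27 interferon-response genes were higher, by a mean of 1.24 (adjusted p = 6.34e-13, and adjusted p = 0.278 with an estimated correlation), with OAS3 at 26.8 ± 7.16 against 7.09 ± 0.176. Of 15 antigen-presentation genes 13 were higher (adjusted p = 6.88e-07, and adjusted p = 0.278 with an estimated correlation). All these counts were the same adjusted over the list alone. Of 19 matrix proteases 12 were higher and HTRA1, named after its values were seen, was lower, and 13 and 1 adjusted over the list alone (adjusted p = 2.57e-06, and adjusted p = 0.0549 with an estimated correlation). MMP1 was at 184 ± 31.8 against 10.9 ± 0.296, and MMP13 at 47.0 ± 11.4 against 2.14 ± 0.364. Relative to the IL-1β libraries, the interferon list stood at -0.357 in PBSL 1 and at -1.15 in PBSL 2.

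All 18 genes of G2/M phase and mitosis were higher, by a mean of 0.588 (adjusted p = 2.76e-09, and adjusted p = 0.278 with an estimated correlation), with AURKA, a mitotic kinase, at 94.9 ± 11 against 52.3 ± 3.81. Of 18 G1/S genes 8 were higher (adjusted p = 0.0119, and adjusted p = 0.687 with an estimated correlation), with RRM2, a subunit of ribonucleotide reductase, at 144 ± 21.2 against 79.8 ± 8.46. The G1/S call was lost without untreated 3 (adjusted p = 0.0586) and without PBSL 2 (adjusted p = 0.0809), in a range of 3.16e-05 to 0.0809. All 6 metallothionein and zinc genes were higher (adjusted p = 3.08e-05, and adjusted p = 0.0805 with an estimated correlation), and 7 of 12 apoptosis regulators were higher and 1, BCL2L1, lower (adjusted p = 0.00488, and adjusted p = 0.0847 with an estimated correlation). These counts were the same adjusted over the list alone. Of 20 glycolysis and hypoxia genes 15 were higher, and 17 adjusted over the list alone (adjusted p = 7.07e-07, and adjusted p = 0.135 with an estimated correlation). Of 20 sterol synthesis genes 2 were higher and 9 lower, and 4 and 10 adjusted over the list alone (adjusted p = 0.0484, and adjusted p = 0.687 with an estimated correlation). The sterol call was lost without untreated 1, untreated 2, IL-1β 1, IL-1β 2, IL-1β 3, PBSL 2 or PBSL 3 (adjusted p = 0.0924, 0.0644, 0.0546, 0.0521, 0.0502, 0.11 and 0.0591 in this order), in a range of 0.00457 to 0.11.

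The 12 lists above were the called ones, and library means did not overlap between the groups for 10 of them; the exceptions were the G1/S and sterol lists. In the fibrillar and pericellular matrix list 7 genes were higher and 12 lower, and 8 and 12 adjusted over the list alone, and the list was not called (adjusted p = 0.11) except without PBSL 1 (adjusted p = 0.0205, in a range of 0.0205 to 0.472).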

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

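Median-ratio rescaling, quantile normalization and removal of the trend on length and GC content were chosen only after the results were seen; the other alternatives were planned. The planned count-based alternatives were not run, because the values are not counts. Absolute depth is unknown, so no limit from it can be given. Relative depth was estimated from the most frequent ratio of low values to those of untreated 1, taking these values to stand for a few reads. It was 0.946 to 1.13 in the other libraries. The bootstrap range of the log2 ratio was as wide as -0.38 to 0.26, in PBSL 3. No gene or list named here reversed its direction with a call. Leaving aside the requirement of a 2-fold change, the call was the same under every other setting of the gene test that gave a value for 88 of 94 named genes in IL-1β against untreated cells, 87 of 112 in PBSL against IL-1β and 67 of 67 in PBSL against untreated cells. The filter at 5 gave a value for only 84, 102 and 59 of these genes. Of 33 lists the call was the same for 29, 27 and 22 in the same order under the alternatives at the preset correlation, which leave out the estimated correlation and fry. Calls lost or gained without a single library are given with the comparisons for the genes discussed there, and others are counted here; the cause was not tested. Uncalled lists in PBSL against untreated cells that gained a call were NRF2 targets without PBSL 1 (adjusted p = 0.0169), with quantile normalization (0.0433) and with the length and GC trend removed (0.0282), in a range of 0.0169 to 0.0848. Others were heat shock without PBSL 1 (0.0497, range 0.0497 to 0.229), ribosomal proteins without untreated 2 (0.0173) and with the length and GC trend removed (0.000588, range 0.000588 to 0.302), and oxidative phosphorylation with that trend removed (0.00621, range 0.00621 to 0.322). The ATF4 list gained one without PBSL 2 (0.0431) and with no filter (0.0455), in a range of 0.0431 to 0.786. With no filter macrophage, prostaglandin and adipocyte and muscle lists did too (0.0455 each), with ranges of 0.0455 to 0.154, 0.0455 to 0.145 and 0.0455 to 0.0737, and the adipocyte and muscle list also without PBSL 1 (0.0497). In PBSL against IL-1β that list gained a call with no filter (0.045, range 0.045 to 0.0916). For lists, no filter changed only the other genes they were compared with. Each list kept just its members that had passed the filter.

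Requiring a fitted 2-fold change with 1 added to each value left 266 genes higher and 65 lower with IL-1β, 0 higher and 18 lower with PBSL against IL-1β, and 202 higher and 135 lower with PBSL against untreated cells, by construction. It left 14 genes raised and then lowered, and 0 lowered and then raised, 0 raised further and 0 lowered further. With an estimated correlation 7, 0 and 2 lists were called in the 3 comparisons, against 18, 17 and 12 with the preset one. The covariance of the fold changes, -0.025, was -0.0352 with a pseudocount of 0.1, -0.0145 with 5, -0.0181 with no filter and -0.0277 with a filter at 5, and the cause was not tested. Genes lowered and then raised, 265, numbered 175 with no filter and 578 with the length and GC trend removed. That correction also gave 2859 genes lower with IL-1β in place of 1903, and the cause was not tested.

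Leaving out 1 library at a time has fewer residual degrees of freedom. The genes called ranged from 1505 to 2128 higher and 1430 to 2145 lower with IL-1β, from 650 to 2019 higher and 664 to 1885 lower with PBSL against IL-1β, and from 2055 to 2948 higher and 1857 to 2465 lower with PBSL against untreated cells. The highest counts for PBSL against IL-1β came without PBSL 1 and the lowest without IL-1β 2. Genes raised and then lowered ranged from 269 to 725, lowered and then raised from 95 to 480, raised further from 30 to 158 and lowered further from 94 to 381. The covariance ranged from -0.0291 without PBSL 1 to -0.022 without PBSL 2. Called lists ranged from 17 to 18, from 17 to 18 and from 11 to 16. A replicate block moved no count by more than 1.5 times. Residuals of libraries that share a replicate number correlated at -0.225 to 0.0681, and 0 of 9 pairs exceeded 0.1.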

Other observations

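All tests in this part except the splits of the libraries were chosen only after the result was seen.

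A list of 16 genes of the actin and contractile apparatus was written after several of them had been seen to fall with PBSL, so no test of it is given. Of these, 13 fell with PBSL against IL-1β, and the mean log2 fold change over all 16 was -0.55. ACTA2 had means of 141 in untreated cells, 59.5 with IL-1β and 31.1 with PBSL, and TPM2, a tropomyosin, had 42.8, 42.2 and 24.3. Of 8 genes linked to the coactivator YAP, chosen in the same way, 6 fell, and the mean over all 8 was -0.369. CTGF and CYR61 among them also belong to the fibrillar and pericellular matrix list, so the sets are not separate. CYR61, now named CCN1, had means of 254, 270 and 181.

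PBSL 1 lay between the IL-1β libraries and the other PBSL libraries. The distance of PBSL 1 to the nearest IL-1β library was 1.6 times the largest distance between IL-1β libraries. This argues against an IL-1β library under a wrong label, but only by the narrow spread of the IL-1β group. Pairs of untreated libraries differed by 0.0795 to 0.0917, not far below the 0.098 of PBSL 1. PBSL 1 was still nearer to the IL-1β libraries (median absolute log2 difference 0.098 to 0.103) than to the other PBSL libraries (0.119 to 0.134). PBSL 2 and PBSL 3 differed by 0.124. Of 18 lists called with PBSL 1 left out, it lay beyond all IL-1β libraries on the PBSL side in 17. A mixture with RNA of cells given only IL-1β would move every gene the same share of the way, and against PBSL 2 the shares were 0.419 for interferon, 0.494 for cell-cycle and 0.59 for fibrillar matrix genes, and against PBSL 3 0.531, 0.468 and 0.607. Interferon minus cell-cycle genes gave -0.0756 (95% bootstrap interval -0.2 to 0.033) against PBSL 2 and 0.0634 (0.00266 to 0.183) against PBSL 3. Cell-cycle minus matrix genes gave -0.0961 (-0.234 to -0.00501) and -0.14 (-0.246 to -0.0702) in the same order. Interferon minus matrix genes gave -0.172 (-0.344 to -0.0583) and -0.0765 (-0.184 to 0.0709). The bootstrap drew the genes of each list anew and kept the libraries fixed. Genes of a list were correlated (estimated at 0.779 for interferon and 0.537 for fibrillar matrix genes), so the intervals are too narrow. The shares differed by less than the 0.2 set as the bound for exclusion, with some intervals that reach past it. A mixture and a lower effective exposure to PBSL thus cannot be told apart, and the amount per library is not given.

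Of 27 interferon-response genes 22 fell with PBSL, while of 23 NF-κB genes 3 fell, 1 rose and 19 were not called. The camera call of the interferon list was lost with an estimated correlation (adjusted p = 0.229). If a weaker IL-1β stimulus lowered both lists in proportion to their rise, they would lose like shares. Of the mean log2 rise, the PBSL libraries lost 2.51 ± 1.03% in the NF-κB list and 37.8 ± 19.9% in the interferon list (SD, 3 libraries). These shares argue against a proportional loss only. Whether a weaker stimulus would act in proportion was not tested, so a weaker stimulus as such stays open. The median-ratio factors ran only from -0.024 to 0.0344 on the log2 scale, and the interferon mean was -0.787 after rescaling. With the length and GC trend removed the interferon mean was -0.759. Neither such factors nor that trend is thus the whole cause. The difference between the lists had p = 0.0941 with an estimated correlation, and the test did not separate interferon genes from chemokines (p = 0.257 with the preset correlation), so an effect on interferon genes alone is not shown. No biological explanation was tested.

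All 18 G1/S and all 18 G2/M genes rose with PBSL, and of 20 fibrillar matrix genes 16 fell and 4 were not called. The mean log2 fold changes of the 36 cell-cycle and 20 matrix genes differed by 0.997. The calls of all 3 lists were lost with an estimated correlation (adjusted p = 0.183 each). Median-ratio rescaling uses 1 factor per library and shifts both sets of genes alike. It could hardly change this difference, which was 0.996 after it, so nothing is read from that value. With the length and GC trend removed the difference was 0.941, against a spread of 0.325 between the PBSL libraries. That trend is thus excluded as the whole cause. Cell numbers and density at harvest were not used here, and no biological explanation was tested.

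The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. The real split called 3831 genes with IL-1β, 2684 with PBSL against IL-1β and 4965 with PBSL against untreated cells, and the highest other split called 0, 1 and 0. For lists the real splits called 18, 17 and 12 and the highest others 17, 16 and 12. For lists in PBSL against untreated cells 3 of 10 splits called as many, and in each other count 1 of 10 did. With IL-1β against untreated cells every other split called at least 10 lists. In PBSL against IL-1β the counts of 15 and 16 came from splits that set PBSL 1 apart from PBSL 2 and PBSL 3. The number of lists called thus hardly sets the real groups apart from mixed ones. The real split gave 513 genes raised and then lowered and the highest other 1. Each other split mixes libraries of both groups, so their difference adds to the residual spread and few genes can be called. The low gene counts of the other splits thus say nothing about chance.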
